A study of Mus musculus with 6 samples.

How the data were processed

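Polyadenylated RNA of fully-grown GV oocytes was measured in 3 WT and 3 Rtcb KO libraries, grouped by the genotype in the labels. Per the labels' protocols, 10 oocytes per library were lysed in a buffer with ERCC spike-in RNA, cDNA was made by Smart-seq2, a full-length cDNA method with oligo-dT priming, and libraries were sequenced as paired ends on an Illumina instrument. Per the submitters' processing notes, TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the mouse build mm9; the annotation and filters are not given in the sources used here.

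The deposited values are FPKM per gene symbol, normalized by the authors to the ERCC spike-ins, per the labels. The table holds 23235 gene rows, 4682 of them at 0 in every library, 0 spike-in rows and 0 duplicated symbols. How the spike-in factors were derived is not given in the sources used here, so the values were searched for them. Cufflinks values carry 6 significant digits, and 442 candidate fractions were tried for the one that turns values of at least 1 back into such numbers (tolerance 0.01 of the last digit). The WT values did so after division by 2 and the KO values after division by 4/3, for 100% of values in every library, against at most 76.8% for any next fraction. The factors hold up to powers of 10. Each genotype thus carries one factor, at a KO to WT ratio of 0.667, and spike-in error between replicates is not part of the spread between libraries.

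Genes with a mean of at least 1 FPKM over the 6 libraries (12029) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Library sums were compared by an exact permutation test, two-sided. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, and with camera at an estimated correlation and fry as alternatives. The limma step was tested on simulated data with 12029 genes. Only 68, 66 and 66 genes were changed, by 0.6, 1 and 2, as many up as down. They were drawn from genes above a set mean level, with independent noise. In the data 63.3% of genes were called, most of them lower, so the simulated rates do not carry over to this comparison. In that simulation limma recovered 36.8% of genes changed by 0.6, 65.2% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, with 5 false calls among 11829 unchanged genes.

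Genes were named by a rule. Rtcb, Ddx1, Xbp1 and Ern1 were always named. Next came the 12 largest rises and the 12 largest falls among called genes whose 3 KO values lay all above or all below the 3 WT values and whose higher group mean was at least 5 FPKM, leaving out predicted, Rik, microRNA and snoRNA symbols. Last came up to 4 members of smallest p per list. The rule, the lists, the tests and most alternatives were fixed before the data were examined. In all, 5891 genes met the conditions for the largest changes. Results of 2 genes are not reported here. Genes outside the rule are said to be named after their values were seen. The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 10 FPKM, rescaling to equal totals and by median ratios, no intensity trend, a replicate block, each library left out in turn, and for sums the omission of the 100 highest rows or of rows with a mean under 10. Removal of the genotype factors and omission of short RNA genes (108 tested), whose FPKM are unstable, were added after seeing the data, as were the alternatives for group overlap and for ratios of means.

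Exon numbers, lengths and GC content came from GENCODE vM21, an annotation of build mm10, matched by symbol for 98.6% of tested genes. They were used for gene properties only; no coordinates are given because the annotation's build differs from that of the values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Reads, isoforms and splice junctions were not analysed here. Read counts are not part of the values used, so depth and counting error per library are unknown.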

Results

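Transcript levels were measured in fully-grown germinal vesicle (GV) oocytes, the meiotically arrested oocytes present before ovulation, of C57BL/6 mice. Oocytes were wild type (WT) or carried a knock-out of Rtcb (Rtcb KO), the gene of the RNA ligase that joins tRNA exons and the cleaved Xbp1 mRNA. There were 3 libraries per genotype, each made from 10 oocytes, and the design has this single contrast. The series concerns alternative splicing of mRNA and the development and maintenance of oocytes; the values used here are per gene, so isoforms, splice sites and the spliced form of Xbp1 were not analysed here. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Values are spike-in (ERCC) normalized FPKM, given as mean ± SD (n = 3). Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Read depth per library is unknown, because FPKM from Cufflinks do not keep it.

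Rtcb itself, listed under its older symbol D10Wsu52e, was at 136, 133 and 113 FPKM in the 3 WT libraries and at 3.82, 2.62 and 2.49 FPKM in the 3 KO libraries. Its mean fell from 127 ± 12.9 to 2.98 ± 0.733 FPKM (log2 fold change −5.02, SE 0.157, limma adjusted p = 1.36e-05), 42.7-fold by the means. All 3 KO libraries therefore carried their labelled genotype at the level of this transcript. Which part of the gene was deleted is not given in the sources used here.

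Partners of RTCB in the tRNA ligase complex moved in both directions. Ddx1, the helicase of the complex, fell from 34.1 ± 5.86 to 13.8 ± 2.03 FPKM (log2 fold change −1.25, adjusted p = 0.000403), and Fam98b fell from 21.4 ± 4.92 to 8.10 ± 1.41 FPKM. Fam98a, its paralog, rose from 21.6 ± 3.42 to 40.9 ± 8.36 FPKM. Of 6 tested partners, 1 rose and 4 fell, with the same counts adjusted over the list alone. The other 2 that fell were Rtraf, listed as 2700060E02Rik (297 ± 20.2 to 239.7 ± 10.1 FPKM), and Zbtb8os, named after its values were seen (46.7 to 30.9 FPKM). Both turn positive with the genotype factors removed (log2 fold changes 0.28 and 0.0056), where 2 partners rose and 2 fell. Their calls were also lost without single libraries: Rtraf without KO 3 (adjusted p = 0.0595) and Zbtb8os without 3 of the 6 libraries (up to 0.104, without KO 3).

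Genes were compared between the genotypes to ask which transcripts differ when Rtcb is lost. Among the genes named by rule for the largest rises on the log2(FPKM + 1) scale, Id3 came first (10.5 ± 3.35 to 158 ± 64.1 FPKM, log2 fold change 3.76). By the ratio of means Itm2a (56.1-fold) and Gsto2 (48.1-fold), both under 1 FPKM in WT, rose more than Id3 (15.1-fold). These ratios are unstable: Itm2a ranged from 34.4-fold (without KO 3) to 82.1-fold (without WT 2) and Gsto2 from 33.1-fold (without KO 2) to 89.0-fold (without WT 1). Id2 rose too (9.44 ± 0.736 to 69.8 ± 10.8 FPKM, log2 fold change 2.75), and Id2 and Id3 both encode inhibitors of basic helix-loop-helix transcription factors. The histone variant gene H2afz rose 6.31-fold (101 ± 11.6 to 636 ± 163 FPKM) and Clp1, the RNA kinase that associates with the tRNA splicing endonuclease, rose 7.89-fold (3.31 ± 1.92 to 26.1 ± 9.64 FPKM). Among the genes named for the largest falls were Dnmt1, the maintenance DNA methyltransferase (622 ± 46.1 to 136 ± 15.5 FPKM, log2 fold change −2.19), and Padi6, needed for the oocyte's cytoplasmic lattices (3392 ± 689 to 746 ± 152 FPKM, log2 fold change −2.18). The remaining named rises, with log2 fold changes from 2.59 to 3.63, were those of Gsto2, Itm2a, Zfp707, Tex19.2, Zfp622, Zfp367, Slc39a1 and Plekhf2. The remaining named falls, from −2.64 to −2.19, were Prelid2, the chemokine gene Ccl2, the keratin genes Krt76 and Krt25, Cd200, Dcpp3, H2-Aa, Defb41 and D4Bwg0951e, a former symbol of Lurap1l. Prelid2 was at 4.07, 11.997 and 8.74 FPKM in WT, at 1.67 FPKM in KO 1 and listed at 0 in KO 2 and KO 3. Dcpp3 has near-identical copies, so its value is uncertain.

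**Figure D1:**
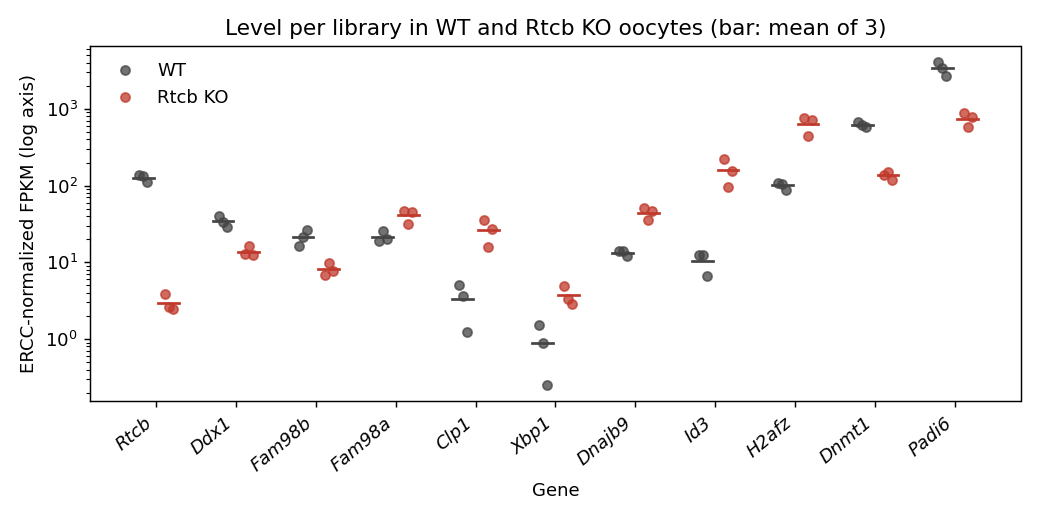
Each point is one library's ERCC-normalized FPKM (log axis), and each bar the mean of 3 libraries, for 11 genes in WT (grey) and Rtcb KO (red) oocytes. Rtcb lies between 113 and 136 FPKM in WT and between 2.49 and 3.82 FPKM in KO, and Fam98a, Clp1, Xbp1, Dnajb9, Id3 and H2afz are higher in every KO library than in any WT library.

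Of 12029 tested genes, 7619 (63.3%) differed between the genotypes by limma at an adjusted p under 0.05, 1118 higher and 6501 lower in Rtcb KO. A change of at least 2-fold was called for 2230 genes, 437 higher and 1793 lower. The groups did not overlap for 8150 tested genes as deposited (67.8%), part of which the scaling sets. With equal totals these were 6859 (57.0%), and with the genotype factors removed 6785 (56.4%), where random groupings of alike libraries give 10%. The median of all tested genes was −0.47 on the log2 scale, and gene groups are compared with that shift below. This split between higher and lower genes changes with the scaling. All 3 WT columns carry one common factor and all 3 KO columns another, at a KO to WT ratio of 0.667 (−0.58 on the log2 scale). Unless stated otherwise, FPKM and fold sizes of single genes, above and below, are as deposited, so the folds include this ratio. With both factors removed, an alternative added after the data were seen, 5258 genes differed, 3097 higher and 2161 lower, and the median was 0.043. With every library rescaled to the same total, 5390 differed, 2283 higher and 3107 lower (median −0.094), and with median-ratio rescaling 5352 differed, 2746 higher and 2606 lower. Under the deposited, equal-total and factor-removed scalings alike, 1110 genes were higher and 2161 lower, of which 428 and 147 changed at least 2-fold in each. Another 87 genes were lower as deposited and higher with the factors removed.

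**Figure D2:**
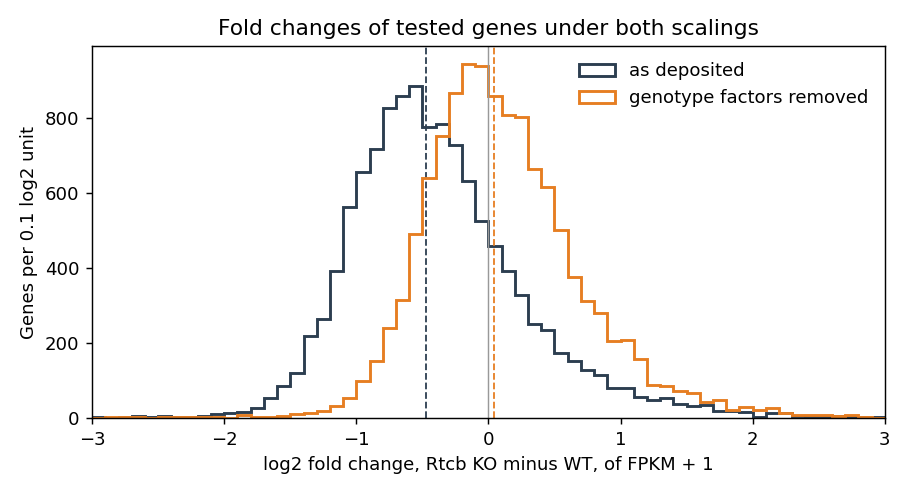
Number of tested genes per 0.1 unit of log2 fold change (Rtcb KO minus WT, of FPKM + 1) for the values as deposited (dark) and with the genotype factors removed (orange), shown from −3 to 3. Dashed lines mark the medians, −0.47 and 0.043.

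The summed FPKM per library was 1310909 ± 40113 in WT and 971498 ± 27793 in Rtcb KO as deposited, a KO to WT ratio of 0.741. With the genotype factors removed, the sums were 655455 ± 20056 and 728623 ± 20845, a ratio of 1.11 in the opposite direction. In both cases the 3 libraries of one genotype lay apart from the 3 of the other (exact permutation test, two-sided, p = 0.1 for each), which is the smallest p that 3 against 3 can give. The order as deposited follows from the genotype factors, since it turns without them. Without the factors, FPKM are relative to each library's own reads, so the ratio of 1.11 is not an amount of mRNA. Spearman correlations across genes, which are not independent replicates, ran from 0.969 to 0.981 within genotypes and from 0.915 to 0.946 between them. The first principal component of the deposited values, into which the genotype factors enter, held 64.2% of the variance and separated the genotypes. KO 2 lay nearer to WT on it (35.8) than KO 1 (48.2) and KO 3 (49.4), and the WT libraries lay between −45.4 and −43.4.

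Of the 26 gene lists, fixed before the data were examined, 25 had enough tested members for camera, which compares a list with all other genes. Camera called 2 lists: ribosomal protein genes stood above the other genes, and maternal-effect genes below them. With no filter it called 6 more that missed the threshold here: meiotic cell cycle, double-strand break, spliceosome, chromatin, proteasome and ER chaperone genes. Without the filter, genes near 0 FPKM join the comparison, and the median of all tested genes moves from −0.47 to −0.19. Camera calls with no filter, here and below, may therefore carry the shift of expressed genes. With an estimated correlation between genes camera called 0 lists, with 1, maternal-effect genes, at an unadjusted p under 0.05 (adjusted p = 0.447). Fry, which tests whether the genes of a list move one way without comparing them with others, called 24 lists as deposited. Most tested genes were lower there, so these calls carry that shift. Members named for a direction with 5 or fewer calls were chosen after their values were seen, unless they are among the 4 of smallest p.

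Maternal-effect genes, whose products the early embryo draws from the oocyte, were lower in Rtcb KO. Besides Dnmt1, the members of smallest p were Nlrp14 (2318 ± 486 to 600.1 ± 71.8 FPKM, log2 fold change −1.93), Tet3, which oxidises methylated cytosine (187 ± 24.5 to 52.8 ± 9.26 FPKM), and Nlrp4f (759 ± 73.9 to 291 ± 29.8 FPKM). Padi6, also a member, fell further than these 3 (log2 fold change −2.18). Of 44 tested members, 0 rose and 35 fell by limma (0 and 36 adjusted over the list alone, and 0 and 36 at an unadjusted p under 0.05). With equal totals 4 rose and 20 fell, and with the genotype factors removed 6 rose and 19 fell. The list median was −0.72, or −0.25 relative to all genes (camera adjusted p = 0.0148; adjusted p = 0.447 with an estimated correlation). The estimated correlation was −0.0081, below the preset 0.01, so higher correlation among members is not why the call was lost there. The call was also lost among genes with a mean of at least 10 FPKM (camera adjusted p = 0.119). Some Nlrp genes have close paralogs, so reads could be shared between them, which was not tested.

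Cytosolic ribosomal protein genes stood above the other genes, at a median of 0.045, which is 0.52 above that of all genes. Of 80 tested members, 8 rose and 4 fell as deposited (2 and 3 adjusted over the list alone), while 64 rose and 1 fell with equal totals and 72 rose and 1 fell with the genotype factors removed. Rpl9 rose from 35.4 ± 3.52 to 109.6 ± 31.8 FPKM and Rpl37 fell from 1604 ± 219 to 654 ± 190 FPKM under all of these scalings. Rpl4 and Rpl5, also lower as deposited, turn positive with the factors removed (log2 fold changes 0.19 and 0.046). Camera called the list (adjusted p = 1.74e-07), but not with an estimated correlation (adjusted p = 0.879), and fry did not (adjusted p = 0.757). These genes have many processed copies in the genome, so single values are uncertain.

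Genes of the unfolded protein response differed in direction. Xbp1, the transcription factor mRNA spliced by IRE1 and RTCB, rose from 0.887 ± 0.631 to 3.70 ± 1.02 FPKM (log2 fold change 1.35, adjusted p = 0.00361), and Dnajb9, a chaperone of the endoplasmic reticulum (ER) induced through XBP1, rose 3.35-fold (13.3 ± 1.08 to 44.6 ± 8.20 FPKM). The Xbp1 ratio of means, 4.17, is unstable and ranged from 3.07 (without WT 3) to 6.44 (without WT 1). Ern1, which encodes IRE1, fell from 46.4 ± 5.74 to 26.4 ± 1.501 FPKM, a call lost with equal totals (adjusted p = 0.0585), median-ratio rescaling (0.091) and the factors removed (0.173). Of 6 tested UPR sensors, 1 rose and 5 fell, with the same counts adjusted over the list alone; 1 rose and 1 fell with the factors removed. The one that rose was Eif2ak3, which encodes PERK (2.43 to 5.15 FPKM; call lost without 3 libraries, adjusted p up to 0.0674 without KO 3). Besides Ern1, those that fell were Atf6 (18.1 ± 2.28 to 8.36 ± 0.25 FPKM), Atf6b, Mbtps2 and Mbtps1. The last of these lost its call without 5 of the 6 libraries (up to 0.146, without WT 1), and with the factors removed Atf6 alone kept its own.

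Most ER chaperone genes were lower. Pdia4, a protein disulfide isomerase, fell 3.22-fold (129 ± 19.6 to 39.97 ± 5.56 FPKM), Hsp90b1 2.499-fold (185 ± 9.73 to 73.9 ± 8.43 FPKM), Canx 2.33-fold (136 ± 8.62 to 58.2 ± 3.02 FPKM) and Dnajc3 2.30-fold. Of 23 tested members, 2 rose and 19 fell, also adjusted over the list alone (3 and 8 with the factors removed; camera adjusted p = 0.253). Those that rose were H47, of ER-associated degradation (1.36 to 12.4 FPKM), and Ero1l (1.13 to 3.13 FPKM; call lost without 3 libraries, adjusted p up to 0.0648 without KO 3). The H47 ratio of means, 9.08, is unstable and ranged from 6.98 (without WT 3) to 18.6 (without WT 1). Of 29 XBP1-dependent secretory genes, 5 rose and 17 fell, also adjusted over the list alone (11 and 6 with the factors removed). Dnajb9, Spcs3, Ostc and Srp19 were among the 5 that rose, and Sec61a1 (97.6 ± 10.3 to 42.1 ± 4.77 FPKM) and Sec31a among those that fell; Srp19 lost its call without 4 libraries (up to 0.133, without KO 1). Camera placed this list up (adjusted p = 0.952), while its median lay −0.024 below that of all genes and its mean 0.038 above that of all genes. Of 26 tested genes of the ATF4 stress response, 1 rose and 16 fell, also adjusted over the list alone (6 and 6 with the factors removed; camera adjusted p = 0.879). Chac1, a glutathione-degrading enzyme, rose from 7.08 to 21.1 FPKM, and Slc7a11, Cars, Phgdh and Gars fell between 2.13-fold and 2.44-fold.

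Genes of tRNA processing were mixed. Clp1, Tsen15, a subunit of the tRNA splicing endonuclease (1.42 to 6.06 FPKM), and Rpp30, of RNase P (148 to 229 FPKM), rose. The Tsen15 ratio of means, 4.27, is unstable and ranged from 3.165 (without WT 3) to 7.81 (without WT 1). Elac2, the tRNA 3' endonuclease, fell 2.55-fold (62.6 ± 12.9 to 24.6 ± 1.42 FPKM) and Angel2 2.39-fold (199 ± 7.36 to 83.2 ± 12.3 FPKM). Of 22 tested members, 3 rose and 7 fell, also adjusted over the list alone; 11 rose and 2 fell with the factors removed. Trnt1, lower as deposited (98.6 to 70.9 FPKM), turns positive there (log2 fold change 0.11). Camera did not call the list (adjusted p = 0.193).

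Spliceosome, SR protein and hnRNP genes, which bear on the subject of the series, were mostly lower as deposited, like all tested genes (6501 of 12029). Relative to all genes, the list median was −0.046 for spliceosome and 0.0057 for SR protein and hnRNP genes. It was 0.15 for genes of nonsense-mediated decay and the exon junction complex. Srrm2 fell 3.35-fold (38.1 ± 4.46 to 11.4 ± 1.44 FPKM), Eftud2, a U5 snRNP component, 3.05-fold (65.2 ± 12.3 to 21.4 ± 0.483 FPKM), Cwc22 2.504-fold and Sf3b2 2.14-fold. Of 63 tested spliceosome components, 3 rose and 42 fell, also adjusted over the list alone (14 and 14 with the factors removed; camera adjusted p = 0.299). Those that rose were Snrpb (39.1 to 173 FPKM), Txnl4a (83.5 to 114 FPKM) and Prpf4 (3.92 to 7.42 FPKM; call lost without KO 1, adjusted p = 0.0514, and without WT 2, 0.0559). Sf3a1 was the fourth member of smallest p and fell 1.995-fold. Of 54 SR protein and hnRNP genes, 9 rose and 31 fell (9 and 32 adjusted over the list alone; 15 and 7 with the factors removed), with Srrm2, Esrp1, Hnrpdl and Srpk1 among those that fell; Srpk1 lost its call with the factors removed (adjusted p = 0.0734). Camera gave this list an adjusted p of 0.952. Of 19 genes of nonsense-mediated decay and the exon junction complex, 4 rose and 8 fell, also adjusted over the list alone (9 and 1 with the factors removed; adjusted p = 0.563). Ncbp1, Casc3, Pnrc2 and Smg5 rose. Smg5 lost its call without 4 libraries (up to 0.12, without KO 1) and Pnrc2 without KO 1 (0.0576). Smg6 fell 2.12-fold, and Ncbp2, Eif4a3 and Upf3a fell as deposited but were not called with the factors removed.

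Among oocyte growth and zona pellucida genes, Kit, the receptor of KIT ligand, fell 3.31-fold (95.3 ± 11.3 to 28.7 ± 3.72 FPKM) and Zp1 2.17-fold (1459 ± 226 to 672 ± 54.5 FPKM). Figla (127 to 171 FPKM) and Tbpl2 (17.0 to 30.9 FPKM), transcription factors of oocytes, rose. Of 35 tested members, 2 rose and 21 fell, also adjusted over the list alone (11 and 3 with the factors removed; camera adjusted p = 0.879). Oas1d and H1foo, also lower as deposited, were not called with the factors removed (adjusted p = 0.0816 and 0.147).

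Meiotic cell cycle genes included Aurkb, a kinase of the chromosomal passenger complex, which fell 2.86-fold (36.5 ± 0.614 to 12.7 ± 0.175 FPKM), Fbxo43, an inhibitor of the anaphase-promoting complex (2.46-fold), Anapc4 (2.26-fold) and Plk1 (2.19-fold). Of 51 tested members, 1 rose and 40 fell, also adjusted over the list alone (9 and 14 with the factors removed). Wee1, a kinase that inhibits CDK1, rose from 10.4 to 33.2 FPKM. Camera gave an adjusted p of 0.0545, against 0.858 with an estimated correlation. It passed with a pseudocount of 5 (0.0188), with no filter (5.38e-05), without WT 3 (0.0468) and without KO 1 (0.0483), and had 0.141 with equal totals and 0.209 with the factors removed. Among genes of maternal mRNA decay, Edc4 fell 3.23-fold, Eif4enif1 2.76-fold, Cpeb1 2.73-fold and Dcp1a 2.59-fold, while Lsm1 (47.3 to 117 FPKM), Zfp36l2, Ddx6 and Ythdf1 rose. Ythdf1 lost its call without KO 1 (0.0572) and without WT 3 (0.0506). Of 37 tested members, 4 rose and 23 fell (4 and 24 adjusted over the list alone; 9 and 13 with the factors removed; camera adjusted p = 0.563).

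DNA repair and chromatin genes were mostly lower. Parp1 fell 4.45-fold (17.3 ± 1.63 to 3.89 ± 1.01 FPKM), Hus1 2.23-fold, and Xrcc5 and Xrcc6, the Ku subunits, 2.22-fold and 2.06-fold. Of 44 tested double-strand break genes, 1 rose and 31 fell, also adjusted over the list alone (8 and 17 with the factors removed; camera adjusted p = 0.0922, or 0.858 with an estimated correlation, 0.000602 with no filter and 0.0483 without KO 1). The one that rose was Chek2 (3.50 to 5.84 FPKM), which lost its call without 5 libraries (up to 0.126, without KO 1). Of 49 tested chromatin regulators, 3 rose and 34 fell (3 and 35 adjusted over the list alone; 7 and 15 with the factors removed; adjusted p = 0.193). Besides Dnmt1 and Tet3, Uhrf1, which recruits DNMT1, fell 2.83-fold (455 ± 71.2 to 161 ± 6.62 FPKM) and Smarcb1 1.91-fold. Tet2, Ehmt2 and Chd1 rose, all below 8 FPKM, and Chd1 lost its call without 4 libraries (up to 0.0609, without KO 1).

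Oxidative phosphorylation genes were less far below WT than most genes, at a median of −0.20, 0.27 above that of all genes. Ndufv1 of complex I fell 2.09-fold, Atp5a1 1.98-fold, Uqcrc2 1.84-fold and Atp5b 1.74-fold as deposited, while Uqcrb, Uqcrc1 (13.2 to 31.9 FPKM) and Atp5g3 rose. Of 77 tested members, 3 rose and 28 fell (3 and 22 adjusted over the list alone), against 34 and 8 with equal totals and 44 and 6 with the factors removed. Camera did not call the list as deposited (adjusted p = 0.407) but called it with equal totals (0.000401), median ratios (0.000536) and the factors removed (0.000122). With an estimated correlation it was not called as deposited (0.9985), with equal totals (0.968) or with the factors removed (0.910). Atp5b was not called with the factors removed (0.0769).

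Other lists of general cell functions were mostly lower as deposited and none was called by camera. Of 43 tested RNA polymerase II and general transcription factor genes, 4 rose and 26 fell, also adjusted over the list alone (13 and 6 with the factors removed; adjusted p = 0.952). Supt6h, Gtf2a1, Polr2b and Taf6 fell, and Polr2h, Cdk9, Ccnt1 and Tbpl2 rose. Of 18 RNA exosome genes, 2 rose, C1d and Exosc6, and 14 fell (2 and 15 adjusted over the list alone; 3 and 2 with the factors removed; adjusted p = 0.589), among them Skiv2l2 and Exosc10; Zcchc8 and Rbm7 also fell but were not called with the factors removed. Of 36 proteasome genes, 3 rose and 26 fell (4 and 28 adjusted over the list alone; 11 and 8 with the factors removed; adjusted p = 0.407). Psmd2 fell 2.87-fold, Psmd1 2.71-fold, Psmd6 2.08-fold and Adrm1 1.79-fold. Psmd13, Psmb5 and Psmd7 rose, with calls lost without 3, 5 and 5 libraries (adjusted p up to 0.0748 without KO 3, 0.143 without KO 3 and 0.164 without KO 1). Of 35 autophagy and lysosome genes, 4 rose and 18 fell, also adjusted over the list alone (7 and 4 with the factors removed; adjusted p = 0.998). Ctsl (3.87 to 18.3 FPKM), Neu1, Ulk2 and Gla rose, Ulk2 and Gla with calls lost without 3 and 4 libraries (up to 0.0577 without WT 2 and 0.123 without KO 3). Pik3c3 and Lamp1 fell. Atg5 and Atg4b fell as deposited but were not called by limma with the factors removed (log2 fold changes −0.22 and −0.085, adjusted p = 0.0886 and 0.45).

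Of 28 tested p53 targets, 1 rose, Sesn1 (1.25 to 4.77 FPKM), and 14 fell (1 and 13 adjusted over the list alone; 7 and 6 with the factors removed; adjusted p = 0.998). Mdm2 fell 2.35-fold, Btg2 2.08-fold and Rrm2b 1.97-fold, and Psrc1 fell 1.65-fold as deposited but was not called with the factors removed (adjusted p = 0.251). Of 12 tested interferon and RNA-sensing genes, with 21 more below 1 FPKM, 0 rose by limma and 5 fell, also adjusted over the list alone and at an unadjusted p under 0.05 (3 and 2 with the factors removed; adjusted p = 0.998). Ddx58 fell 2.33-fold and Cmpk2 1.95-fold. Oasl1 and Mavs also fell, but each lost its call without single libraries, 2 and 3 of the 6 (adjusted p up to 0.0768 and 0.0639, each without KO 3), and both turn positive with the factors removed (log2 fold changes 0.075 and 0.046). For the p53, interferon, RNA polymerase II, proteasome and RTCB partner lists, as for XBP1-dependent genes, the median, the mean and the camera direction relative to all genes differed in sign.

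Markers of other cells were lower in KO by their sums as deposited. There fry called the granulosa and cumulus list (adjusted p = 0.00514) and the blood and immune list (0.0288) lower. With the factors removed the blood and immune sum was higher in KO. The summed FPKM of 25 granulosa and cumulus markers was 631 ± 14.3 in WT and 305 ± 15.5 in KO (316 ± 7.14 and 229 ± 11.6 with the factors removed), most of it from Serpine2 (498 ± 16.3 to 212 ± 23.8 FPKM), Bmpr1b and Cyp19a1, which fell; Cyp19a1 was not called with the factors removed (adjusted p = 0.0565). Of 9 tested members, 1 rose and 3 fell, also adjusted over the list alone (2 and 2 with the factors removed; adjusted p = 0.407). Nr5a2 rose from 9.45 to 13.4 FPKM, a call lost without 4 libraries (up to 0.0999, without KO 1). Inha, named after its values were seen, was not called: it was at 7.28, 8.36 and 3.50 FPKM in WT and at 6.08, 8.13 and 17.8 FPKM in KO. The 16 members not tested had means below 1 FPKM, with Foxl2 at most 0.0763 FPKM and Ptx3 at 0 in every library. The list median was 0.11, or 0.58 above that of all genes, and camera placed the list up, against its sum. The granulosa and cumulus sum is therefore no measure of such cells. The sum of 19 theca, stroma and endothelium markers was 46.5 ± 9.26 in WT and 25.4 ± 2.83 in KO (23.3 ± 4.63 and 19.0 ± 2.13 with the factors removed). Most of it came from Pecam1 (46.7, 38.1 and 30.2 FPKM in WT), while Cdh5, Acta2 and Lum were at 0 in every library. This sum is therefore no measure of such cells. Of 4 tested members, too few for camera, 0 rose and 2 fell by limma, Pecam1 and Tek, also adjusted over the list alone (1 and 2 at an unadjusted p under 0.05; 1 and 0 with the factors removed). Tek lost its call without WT 2 (0.0586), and Cyp11a1 (1.87 to 1.81 FPKM) did not pass. Hsd3b1 (0.501 to 1.99 FPKM) did not pass either, but was called higher under 7 alternatives, among them equal totals (0.0459) and the factors removed (0.0484). Its level was 3.97 FPKM in KO 3 against 1.01 and 0.983 FPKM in KO 1 and KO 2. Its ratio of means fell from 3.97 to 1.99 without KO 3. The sum of 20 blood and immune markers was 281 ± 18.9 in WT and 258 ± 10.3 in KO, but 140 ± 9.45 and 194 ± 7.72 with the factors removed. Nearly all of it came from Srgn and C1qb. Ptprc was at most 0.0803 FPKM and the globin genes were at 0 in every library, so this sum is no measure of blood or immune cells. Of 5 tested members, 0 rose and 2 fell by limma, also adjusted over the list alone (0 and 3 at an unadjusted p under 0.05; 1 and 1 with the factors removed; adjusted p = 0.936). Laptm5 and Srgn fell, Srgn turning positive with the factors removed (log2 fold change 0.20). C1qb (96.1 to 112 FPKM) did not pass as deposited but was called higher with equal totals (log2 fold change 0.66, adjusted p = 0.0133), median ratios (0.74, 0.0048) and the factors removed (0.80, 0.00408). Cd68 did not pass but was called lower without KO 2 (0.0215) and without short RNA genes (0.0434). KO 2 held immune transcripts that the other libraries nearly lacked, named after their values were seen. Cd74 was at 9.52 FPKM in KO 2 and at 0 in the other 5 libraries (not called, adjusted p = 0.253). Below the filter and so not tested, Lyz2 was at 5.46 FPKM there and at most 0.157 elsewhere, and Fcer1g (2.23 FPKM), Tyrobp (1.96 FPKM) and Cd52 (1.02 FPKM) were also highest in KO 2. H2-Aa, an immune gene named above for its fall, was at 4.57 FPKM in KO 2 against 0.73 and 0.715 FPKM in KO 1 and KO 3. Its ratio of KO to WT means was 0.184, and 0.066 without KO 2.

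**Figure D3:**
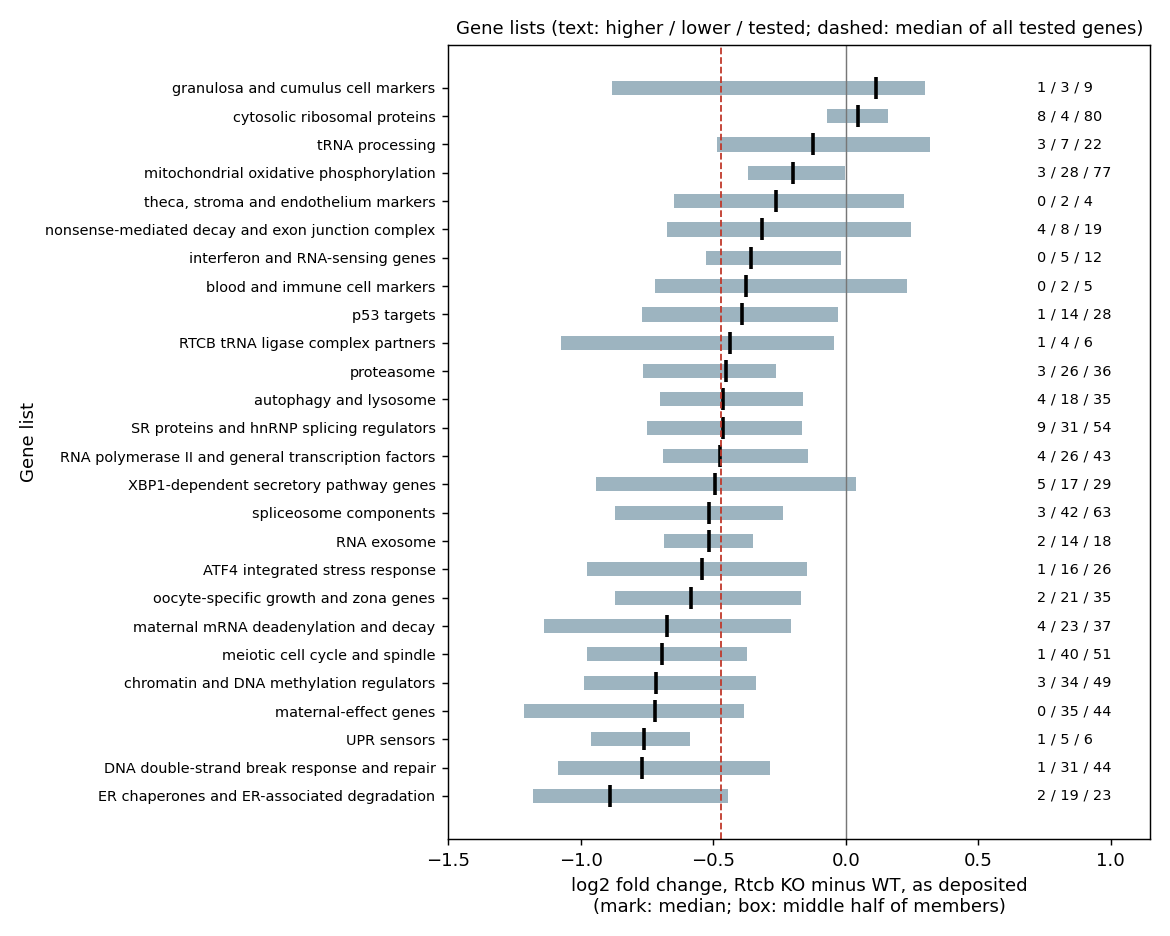
Log2 fold changes (Rtcb KO minus WT, as deposited) of the tested members of 26 gene lists: the mark is the median and the box spans the middle 50% of members. The text gives members higher, lower and tested, and the dashed line is the median of all tested genes, −0.47; ribosomal proteins lie above it by 0.52 and maternal-effect genes below it by 0.25, and the sign of many medians changes with the genotype factors removed.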

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

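Removal of the genotype factors, omission of short RNA genes, and the alternatives for group overlap and for ratios of means were chosen after seeing the data; the other alternatives were planned. Rtcb was lower and called under every alternative run, with log2 fold changes from −5.39 (pseudocount of 0.1) to −4.05 (pseudocount of 5) and, leaving out one library, from −5.17 to −4.93. The count of changed genes stayed within 1.5 times of 7619 throughout, from 5184 to 7786; leaving out one library gave 6523 to 7479. Without single libraries, higher genes ranged from 774 (without KO 3) to 1347 (without KO 2) and lower genes from 5607 to 6240. Of 176 named genes with a call, 155 kept it without each library and 21 lost it without at least 1. Whether the same replicate numbers pair the libraries is unknown. Correlations of their deviations were 0.141, −0.099 and 0.038, and not every library correlated best with its own number. With 3 libraries per genotype this cannot show that pairing is absent. With a replicate block 7540 genes were called, and the directions of p53 targets (adjusted p = 0.978) and of autophagy and lysosome genes (0.997), both uncalled, turned; Cd68 passed (0.0425) and Zbtb8os (0.0507), Srp19 (0.0582), Psmd7 (0.0783) and Gla (0.0648) lost their calls. FPKM without read counts leave the precision of low genes unknown. Except where fewer genes were tested or the scaling itself sets the shift, the cause was not tested. Changed genes of at least 2-fold numbered 966 with a pseudocount of 5, 1416 at a mean of at least 10, 1217 with equal totals, 1229 with median ratios and 1056 with the factors removed. Higher genes numbered 490 at a mean of at least 10, 2283 with equal totals, 2746 with median ratios and 3097 with the factors removed; lower genes 3107, 2606 and 2161 under the last 3. The median was −0.33 with a pseudocount of 5, −0.19 with no filter, −0.56 at a mean of at least 10, −0.094 with equal totals, −0.0196 with median ratios and 0.043 with the factors removed, and the difference of log2 sums turned from −0.43 to 0.15. Lists called numbered 8 with no filter, 1 at a mean of at least 10, 0 with an estimated correlation, 24 by fry and 2 to 4 without single libraries, 4 being without KO 1.

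Some genes turned positive. With equal totals these were Rtraf, listed as 2700060E02Rik (0.12), Rpl4 (0.037) and Srgn (0.052). With median ratios they were 2700060E02Rik (0.21), Trnt1 (0.038), Rpl4 (0.12), Oasl1 (0.016) and Srgn (0.13). With the factors removed they were 2700060E02Rik (0.28), Zbtb8os (0.0056), Trnt1 (0.11), Rpl5 (0.046), Rpl4 (0.19), Oasl1 (0.075), Mavs (0.046) and Srgn (0.203). Cyp11a1, never called, turned to −0.0065 with a pseudocount of 5 and ranged from −0.23 to 0.16 without single libraries. Cd74, never called, ranged from 0 (without KO 2) to 1.70 (without KO 1 or KO 3). The camera direction of lists that were not called as deposited turned as follows, with adjusted p. With equal totals it turned for p53 targets (0.946), RNA polymerase II genes (0.946) and interferon genes (0.959). With median ratios it turned for p53 targets (0.973), RNA polymerase II (0.889), proteasome (0.973) and interferon genes (0.973). With the factors removed it turned for oocyte growth genes (0.993), p53 targets (0.948), RNA polymerase II (0.771), RNA exosome (0.993), proteasome (0.948) and interferon genes (0.970). With no filter it turned for RTCB partners (0.807), XBP1-dependent genes (0.63), SR proteins (0.462), oxidative phosphorylation (0.816), interferon genes (0.0715) and autophagy (0.365). At a mean of at least 10 it turned for oocyte growth (0.682) and RNA polymerase II genes (0.68). A pseudocount of 0.1 turned autophagy (0.970), and a pseudocount of 5 turned p53 targets (0.992), interferon genes (0.97) and autophagy (0.992). Without short RNA genes p53 targets (0.999) and interferon genes (0.999) turned. By fry, which does not compare with other genes, the direction was down and called for RTCB partners (0.00085), tRNA processing (0.00384), XBP1-dependent genes (0.00153), SR proteins (0.00123), nonsense-mediated decay (0.00246), oxidative phosphorylation (0.0333), autophagy (0.00505), granulosa markers (0.00514) and blood markers (0.0288). Fry was run on the deposited values only, where the median of all tested genes was −0.47, so these calls carry that shift. With the factors removed the medians of all these lists were positive, from 0.089 (XBP1-dependent genes) to 0.457 (tRNA processing). Leaving out one library turned 6 lists: RNA polymerase II genes without WT 3 (0.989), SR proteins without WT 1 (0.92), blood markers without KO 2 (0.962), p53 targets without WT 1 (0.92) and KO 2 (0.958), interferon genes without WT 1 (0.92), WT 2 (0.969) and KO 2 (0.958), and autophagy without WT 3 (0.967), KO 1 (0.981) and KO 3 (0.922). Over all 6 omissions the adjusted p of these lists ran from 0.888 to 0.989, 0.888 to 0.974, 0.86 to 0.967, 0.92 to 0.989, 0.92 to 0.981 and 0.92 to 0.981, in that order.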

Other observations

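The gene families and their matching, the weighing of the scaling, the tests of mRNA length, coding length and RNA integrity, and the choice of exon number were made only after the results were seen; the other tests were written down beforehand. Grouping the tested genes by the stem of their symbol gave 170 families with at least 8 members. Camera called 6 of them: Rpl, Rps, histones and Snhg stood above the other genes, and Nup and Myo below. With an estimated correlation 0 of the 170 families were called, each of the 6 at an adjusted p of 0.945, with an unadjusted p of 0.0225 for Snhg and 0.0495 for Myo and above 0.05 for the other 4. Nucleoporin genes (Nup), which build the nuclear pore, fell for 18 of 19 members, among them Nup93 (125 ± 14.2 to 40.7 ± 1.63 FPKM) and Nup107 (118 ± 12.04 to 46.5 ± 1.07 FPKM), with 0 higher in the limma test at either an adjusted or an unadjusted p under 0.05 (adjusted p = 0.0127 for the family). Myosin genes (Myo) fell for 16 of 16 members, among them Myo5b (81.5 ± 6.21 to 25.8 ± 2.31 FPKM) and Myo10 (43.03 ± 3.41 to 13.4 ± 0.752 FPKM; family adjusted p = 0.0308). With the genotype factors removed, 10 Nup and 8 Myo genes were still called lower. Both families have many exons (medians of 22.5 and 35.5), and genes with over 20 exons had a median of −0.81, with 76.9% called lower. Among 10000 random lists matched on exon number and coding length, the Myo median (−0.94) lay at percentile 15.4 (15.2 to 16.2 over 10 repeats), within their central 95%. The median of 18 Nup genes with an annotation (−1.02) lay at percentile 0.56 (0.49 to 0.65). Both families were picked from 170 by their calls on these same values, so neither percentile is a test.

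Of 29 replication-dependent and related histone genes, 9 rose and 5 fell as deposited, against 12 and 0 with the factors removed (family adjusted p = 0.000742). Hist1h3c rose from 0.798 ± 0.737 to 9.11 ± 1.27 FPKM, Hist1h1e from 0.448 ± 0.137 to 6.31 ± 2.69 FPKM and Hist1h3g from 5.33 ± 2.14 to 29.4 ± 12.4 FPKM, while the abundant Hist1h2bc fell from 405 ± 28.3 to 232 ± 16.2 FPKM and was not called with the factors removed. Histone genes have near-identical copies, and many of their mRNAs lack the poly(A) tail that the oligo-dT primer needs, so these values are uncertain. Of 9 Snhg genes, which host small nucleolar RNAs in their introns, 4 rose (7 with the factors removed; family adjusted p = 0.000742). These were Snhg1 (33.5 ± 4.57 to 88.1 ± 7.28 FPKM), Snhg6 (182 ± 30.9 to 277 ± 12.5 FPKM), Snhg8 and Snhg12.

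The first pattern weighed is the excess of lower over higher genes in Rtcb KO. Removing the single factor that each genotype carries moves the median of all tested genes from −0.47 to 0.0426, which follows largely by arithmetic from factors that differ by −0.58 and does not test them. A scaling error and less mRNA per oocyte cannot be told apart here, because the table holds 0 spike-in rows. The real grouping gave 7619 changed genes, 1118 higher, 6501 lower and 2230 at least 2-fold, each count reached by 1 of the 10 splits of the libraries into 3 and 3, with at most 2 genes in any other split. Each of the other splits mixes both genotypes on both sides, so the genotype difference enters the spread and low counts were set in advance. They give no rate of false calls. With 10 splits a share under 0.05 cannot be had.

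The second pattern is that log2 fold changes fall with the number of exons, the property with the strongest trend of 7 looked at. Across 11171 protein-coding genes, which are not independent replicates, Spearman's rho was −0.314 (95% bootstrap interval −0.33 to −0.299), and the median went from −0.27 for 217 single-exon genes to −0.81 for 1444 genes with over 20 exons (0.252 and −0.292 with the factors removed). Single-exon genes lay below the 1182 genes with 2 to 3 exons, whose median was −0.212 (0.288 with the factors removed). The trend stayed at −0.273 with mRNA length held fixed, which argues against mRNA length. Coding length had a rho of −0.29 on its own. With it held fixed the trend with exon number shrank to −0.15 (−0.169 to −0.129), which argues against coding length as the whole trend; coding length kept −0.085 at fixed exon number and may carry part of it. The trend was −0.385 among genes with a mean of at least 10 FPKM and a pseudocount of 0.1, which argues against compression of low values. RNA integrity or cDNA length that differs between the genotypes cannot be told apart from an effect of genotype: the labels give no integrity measure, and libraries of one genotype already differ by up to 0.202, against −0.243 to −0.351 between genotypes. Less efficient production or maintenance of multi-exon mRNAs in Rtcb KO may be an alternative, and was not tested, since splice junctions were not analysed here.

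The third pattern is the place of both called lists. With an estimated correlation camera called neither (adjusted p = 0.879 for ribosomal protein and 0.447 for maternal-effect genes). That of maternal-effect genes was −0.0081, so correlation among members does not account for the loss of their call. The maternal-effect call was also lost at a mean of at least 10 FPKM (camera adjusted p = 0.119). The median of ribosomal protein genes, 0.045, lay at percentile 100 of 10000 random lists matched on exon number and coding length and at percentile 100 of lists matched on expression level. The random medians were −0.303 and −0.444, so neither matching alone gave a median as high as that of the list. The 2 were matched separately and in bins, so their joint effect was not tested. Ribosomal protein genes vary together (estimated correlation 0.643), unlike genes of random lists, so the percentiles overstate how rare this place is. The median of maternal-effect genes, −0.72, lay at percentile 1.75 (1.65 to 1.99 over 10 repeats) and at percentile 0.08, against random medians of −0.501 and −0.457. Both lists were picked from 25 by their camera calls on these same values, which makes extreme percentiles likelier. The maternal-effect percentiles therefore do not decide on either matching. RNA quality and genotype stay open for both lists, and reads shared between copies were not tested. The real grouping called 2 lists, while another split called 3 and 6 of the 10 splits called at least 2, and 10 splits are too few for a share under 0.05.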
